A study of Mus musculus with 111 samples.

How the data were processed

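Small RNA of 6 mouse tissues (liver, heart, testis, caput epididymis, cauda epididymis and sperm of the cauda) was sequenced by OTTR-seq, in which a reverse transcriptase joins both adapters while it copies an RNA, so that no separate ligation selects the molecules. Animals had been kept for 6 months on 1 of 4 diets: a control diet with 18% protein, a low-protein diet with 10% protein in which sucrose made up the mass, a high-fat control diet with 7.2% of calories from fat, and a high-fat diet with 60% of calories from fat. The 24 groups of tissue and diet held 4 or 5 libraries each, 111 in all. Groups and replicate numbers came from the sample titles. The labels do not say that libraries of a group came from separate animals, nor which libraries of different tissues share an animal, so the p-values measure the spread between these libraries, part of which can be technical.

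The deposited table gives whole-number read counts per named small RNA for 1268 entries, and the values have no normalization. Per the submitters' processing notes, cutadapt, DESeq2 and the mouse build mm10 were used, with no version or role. The aligner, the counting rule and the treatment of reads that match several copies are not given in the sources used here. The column names end in a code, gt65, whose meaning is also not given. Entries are named per tRNA (amino acid, anticodon and a copy number), mitochondrial tRNA, piRNA precursor or gene. None names a tRNA fragment class, so a full-length tRNA and a fragment of it fall in 1 entry. Of 512 entries with a gene name, 507 matched the GENCODE M21 annotation of GRCm38 (the assembly of mm10), which supplied the class and the coordinates of uniquely named genes. Cytosolic tRNAs have near-identical copies, and the way reads were divided among them is unknown, so values of single cytosolic tRNAs are uncertain. Strand is not stated to have been used for other genes.

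Many reads are listed under more than 1 name. Of 22 mitochondrial tRNAs with a second name, 20 had counts under both that differed by at most 1.09%. The exceptions were mt-tRNA-Arg-TCG-1, with 468611 reads against 25789 under mt-Tr, and mt-tRNA-Ser-GCT-1, with 140 against 386 under mt-Ts2, and the tRNA name was kept for all 22. A further 149 entries, whose summed differences from a kept entry came to less than 5.0% of its total, listed the same reads. The 56 entries of 5S ribosomal RNA were represented by the most abundant, from which 31 of the other 55 differed by less than 5.0% and 24 by more. Entries under 50 reads in total were not compared. The fits used the remaining 1042 entries, called features here, which hold 51.1% of the summed counts. The design written before the data were examined named the entries of the table as the units, and the reduction to 1042 was chosen after the duplicates were seen. The reads per library over these features ran from 827 to 1467880, with a median of 59904. Depth differed between groups. The libraries under 5000 reads were high-fat liver replicate 3 with 827 and low-protein caput replicates 2 and 3 with 2353 and 912, and that limit was set after the depths were seen. None of the 204 pairs of replicates differed by as little as sampling noise, the smallest chi-square per degree of freedom being 1.54, so no library was counted as a repeat. Mature microRNAs are not among the entries, and no cell type marker list was available for such a table, so the cell composition of the samples was not analysed here.

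Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr and the robust quasi-likelihood F test. For diet, 1 fit per tissue held all 4 diets and gave 2 effects, low-protein minus control and high-fat minus high-fat control. For tissues, 1 fit over all libraries had terms for tissue and diet and gave each tissue against the mean of the other 5, sperm against testis, sperm against cauda, and cauda against caput. A separate fit per diet pair held tissue by diet terms and tested whether a diet effect differed among the 6 tissues. The p-values were adjusted by Benjamini-Hochberg within each contrast. A feature was called at an adjusted p under 0.05, and for tissue contrasts also at an absolute log2 fold change of at least 1. Errors of log2 fold changes are standard errors derived from the F statistic. Levels are RPM, the reads of a feature scaled to library size over the kept features, computed from the deposited counts, as mean ± SD over libraries.

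Lists of tRNAs were fixed before the data were examined from amino acid, anticodon and mitochondrial strand, with classes of other small RNA where the table counts them. They were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry. Lists with at least 5 tested members gave 107 list and tissue pairs per diet effect, adjusted together. Selenocysteine and initiator tRNAs and the ribosomal RNA list had too few members. The lists of tRNA fragments and the shares of 5-prime fragments and whole tRNAs that had been planned could not be formed, because the entries have no fragment class. The share of reads from mitochondrial tRNAs was compared between diets by a 2-sided exact permutation test of the difference of means, adjusted over the 6 tissues of a diet effect.

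Named features follow a rule fixed before the data were examined. In each diet contrast these are the 3 largest rises and the 3 largest falls among called features with a mean of at least 100 RPM. Where nothing was called, the 2 smallest p-values at that level are given as not passing. In each tissue contrast they are the 3 highest and 3 lowest called features at that level over all libraries, and the most abundant feature of each tissue is always named. The level was first computed with TMM-scaled library sizes and was changed to plain RPM after the first list had been seen. Where a group held 1 to 3 reads of a named feature, the ratio of summed rates is given with an exact 95% interval. Where it held 0, a bound against a floor of 3 reads over the group is given. Both cover counting error only. The names of most piRNA precursors, which join a chromosome band and a number, are not printed, and only their values are given.

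The fits were tested on simulated counts drawn from the means, spreads and depths of the real libraries, with known changes in up to 200 features. At an 8-fold change the low-protein fits recovered 87.9% of the tested features in liver, 100% in heart and caput, 92.1% in testis, 96.0% in cauda and 95.8% in sperm. At a 2-fold change the values were 5.88% in liver and 3.33% in testis. In the high-fat fit of liver 46.9% of 8-fold changes were recovered. Unchanged features made up at most 8.60% of calls in the diet simulations, and 17.1% in the simulated test of differences between tissues. Raising the snoRNAs of heart alone 2-fold made 6 of the other 20 lists pass, since camera compares each list with all other features.

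Alternatives were DESeq2 1.42.0 (Wald test), RLE factors, total counts, no filter on low counts, only the groups compared, a replicate block, counts summed per anticodon, each library left out, and 4 added after the data had been seen: all entries as deposited, the libraries under 5000 reads left out, differences among tissues without liver and heart, and a block on library number. Replicate numbers recur across groups. The block on replicates within a tissue followed the sample titles. The column names carry a library number, which differs from the title in control liver, high-fat control liver and low-protein cauda (replicates 1 to 4 of control liver and low-protein cauda are libraries 2 to 5), and the blocks across tissues used it. In the high-fat comparison, all 4 same-numbered pairs had deviations from their group means correlated above 0.1 in caput (lowest 0.125) and in cauda (lowest 0.145), so the numbers were taken to pair those libraries, and the block moved neither count by more than 1.5 times. In no other comparison did every pair do so, by either number. Further alternatives were the mitochondrial tRNA share without the most abundant feature of the tissue, its permutation within replicate numbers, and tissue contrasts over the control diets only. Fits of every pair of diets in each tissue were run as exploration before the patterns of the closing part were chosen. Figures and share tests were made in Python 3.11.15 with scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.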

Results

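Small RNA was profiled in 111 libraries from 6 mouse tissues, with 17 libraries of liver, 19 of heart, 19 of testis, 19 of caput epididymis, 18 of cauda epididymis and 19 of cauda sperm. The design asks whether a protein-poor or a fat-rich diet eaten for 6 months alters tRNAs and other small RNAs in somatic tissues, in the male reproductive tract and in mature sperm. The low-protein diet (10% protein) has its own control (18% protein), and the high-fat diet (60% of calories from fat) is set against a high-fat control with 7.2% of calories from fat, although the label of the high-fat diet names 16% as the usual value. Depth varied widely. Median reads per library were 98331 in liver, 492468 in heart, 117899 in testis, 32226 in caput, 62469 in cauda and 32090 in sperm, and the median number of features detected was 354 in liver, 412 in heart, 700 in testis, 294 in caput, 546.5 in cauda and 460 in sperm. Genome positions below are 1-based on GRCm38, and features with a position are annotated as non-coding genes of their own.

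The 6 tissues differed in which small RNAs made up their reads. Heart was dominated by mitochondrial tRNAs, which the mitochondrial genome encodes, at 71.0% ± 13.4 of reads (SD, n = 19), and liver held 45.8% ± 20.9 (n = 17). Testis held 14.5% ± 4.33, caput 29.4% ± 12.2, cauda 9.50% ± 5.15 and sperm 11.8% ± 8.12. Cytosolic tRNAs, encoded in the nucleus, were the largest class of caput (56.9% ± 13.4), testis (45.8% ± 17.7) and cauda (38.3% ± 12.8). In sperm, hairpins annotated as miRNA genes took 30.6% ± 12.4 and 5S ribosomal RNA 11.7% ± 6.21, against 4.37% ± 8.08 and 0.922% ± 0.391 in liver. The hairpin Gm47295, which overlaps Rn7s1, the RNA of the signal recognition particle, made up 3.81% ± 7.43 of the liver reads, with 17.7% and 28.02% in high-fat replicates 3 and 4. Without it the hairpins took 0.559% ± 0.764 in liver and 27.9% ± 11.8 in sperm. In all, 12 hairpins overlap another small RNA of the table on the same strand, so their reads cannot be separated from it. Precursors of piRNAs, small RNAs of the germ line, made up 4.54% ± 3.79 in testis, 0.602% ± 0.329 in sperm and 0.00554% ± 0.00859 in heart. The most abundant feature was mitochondrial mt-tRNA-Val-TAC-1 (chromosome M, 1025 to 1093, plus strand) in liver (24.3% ± 11.7) and heart (31.9% ± 15.4). It was tRNA-Asp-GTC-1 in testis (11.2% ± 4.83), caput (19.2% ± 6.21) and cauda (13.1% ± 3.78), and the 5S ribosomal RNA feature Gm25018 (chromosome 8, 123565969 to 123566087, minus strand) in sperm (11.7% ± 6.21).

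**Figure D1:**
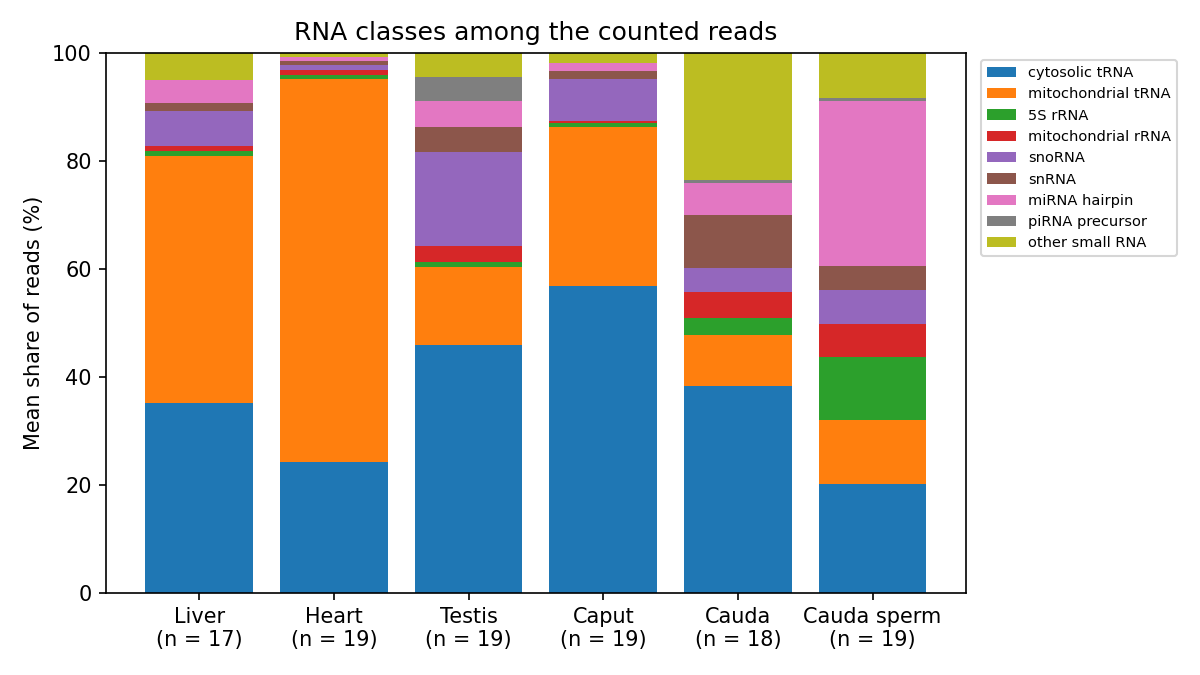
Mean percent of reads per RNA class, stacked, for the libraries of each of the 6 tissues. Mitochondrial tRNAs reach 71.0% in heart, cytosolic tRNAs 56.9% in caput and miRNA hairpins 30.6% in sperm.

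Over the libraries of all diets, liver and heart were set apart from the other tissues by mitochondrial tRNAs. In heart all 21 tested mitochondrial tRNAs were higher, with a median log2 fold change of 4.12. In liver 16 of 21 were higher, with a median of 1.43. For liver the order of shares varied with the diet group. On the control diet the mitochondrial tRNA share was 26.5% ± 3.22 in liver (n = 4), below caput at 46.2% ± 6.96 (n = 5). Liver lay above caput on the low-protein diet (65.5% against 23.5%) and the high-fat control (45.4% against 26.1%). Its mean was also higher on the high-fat diet (41.03% ± 31.7 against 20.1% ± 6.76, n = 4 each). In heart mt-tRNA-Asn-GTT-1 (chromosome M, 5089 to 5159) was higher by 4.80 ± 0.24 (log2, SE), mt-tRNA-Met-CAT-1 (3845 to 3913) by 4.77 ± 0.18 and mt-tRNA-Val-TAC-1 by 4.75 ± 0.20, with 121883 ± 58401 RPM of mt-tRNA-Met-CAT-1 in 19 heart libraries and 30346 ± 32022 in the 92 others. In liver mt-tRNA-Trp-TCA-1 (4950 to 5016) was higher by 2.71 ± 0.26, mt-tRNA-Val-TAC-1 by 2.50 ± 0.22 and the snoRNA Gm26109 (chromosome 18, 34942644 to 34942713) by 2.46 ± 0.31. The U1 spliceosomal RNA Rnu1a1 (chromosome 11, 87422867 to 87423030; log2 −2.19 ± 0.33) and the snRNA Gm24924 (chromosome 18, 14647767 to 14647930; −2.12 ± 0.34) were lower in liver, as were 23 of 26 snRNAs. The hairpin Gm24245 (chromosome 4, 139338304 to 139338360) was lower in liver (−2.90 ± 0.95) and had 2 reads in all heart libraries together, a rate lower than in the other tissues by a ratio of 1460 (interval 404 to 12064). Of the 2807 reads of Gm24245 in those tissues 2100 came from cauda and 580 from sperm, against 12 from liver and 7 from caput, so the ratio reflects cauda and sperm. The piRNA precursors pi-Lpp.2 (−3.99 ± 0.49) and pi-Lpp.1 (−3.65 ± 0.45) were also lower in heart. By edgeR's quasi-likelihood test 108 of 294 features were called in liver (56 higher, 52 lower) and 115 in heart (54 higher, 61 lower), all named ones at adjusted p of 0.00673 or less. The split depended on scaling, since total counts moved the median of all features by −0.41 in liver and −2.29 in heart and called 25 of 105 and 20 of 236 higher, and RLE factors (shifts of −0.40 and −1.54) called 30 of 105 and 25 of 197 higher. Mitochondrial tRNAs stayed higher under all 3 scalings in both tissues (medians in heart 1.66 with total counts and 2.70 with RLE), whereas the median of heart cytosolic tRNAs turned from 0.67 to −1.73 and −0.80.

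Testis stood out by piRNA precursors, of which 39 of 40 were higher than in the other tissues, with a median log2 fold change of 7.02. The 3 precursors that differed most were higher by 8.11 ± 0.35, 8.08 ± 0.36 and 7.97 ± 0.35, and the last of them had 853 ± 826 RPM in testis (n = 19) against 1.63 ± 9.15 elsewhere (n = 92). The snoRNAs, most of which guide chemical modification of ribosomal RNA, were higher in 50 of 105 cases and lower in 12. Mitochondrial tRNAs were lower in 19 of 21 cases, led by mt-tRNA-Asp-GTC-1 (chromosome M, 6942 to 7011; −3.10 ± 0.47), mt-tRNA-Asn-GTT-1 (−3.02 ± 0.37) and mt-tRNA-Ile-GAT-1 (3706 to 3774; −2.90 ± 0.42). The edgeR fit called 173 of 294 features, 110 higher and 63 lower, and the adjusted p of the named features was 2.67e-09 or less. With total counts, which shifted the median feature by 1.39, 192 of 207 were higher, and with RLE (shift 0.98) 158 of 181, while the medians of piRNA precursors (8.36 and 8.11), snoRNAs (2.46 and 1.96) and mitochondrial tRNAs (−0.68 and −1.19) kept their sign.

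In caput, the first part of the epididymis, 35 of 105 snoRNAs were higher than in the other tissues and 10 of 11 miRNA hairpins, 13 of 26 snRNAs and 36 of 74 cytosolic tRNAs were lower. The snoRNAs Gm22193 (chromosome 8, 110842383 to 110842458; 2.71 ± 0.31), Gm24148 (chromosome 1, 86352008 to 86352087; 2.37 ± 0.50) and Gm26109 (2.35 ± 0.29) were the highest. There were 986 ± 1037 RPM of Gm22193 in 19 caput libraries and 157 ± 275 in the other 92. The lowest were tRNA-Leu-AAG-2 (−3.78 ± 0.46), Mir6236 (chromosome 9, 110281287 to 110281409; −3.51 ± 0.46) and the piRNA precursor 9-qC-31469.1, which had 0 reads in caput and was at least 21.4-fold lower there (floor of 3 reads over the group). Of the 1812 reads of 9-qC-31469.1 in the other tissues, 1798 came from testis. The edgeR fit called 139 of 294 features (43 higher, 96 lower), with adjusted p of 0.00400 or less for the named ones. The calls of Gm24148 (log2 1.08, adjusted p 0.240) and of 9-qC-31469.1 (adjusted p 1.00) were lost when only the control diets were used, and DESeq2 did not call 9-qC-31469.1 (adjusted p 0.368). Total counts, with a shift of 0.38, gave 69 of 144 higher, RLE shifted the median by −0.22, and the class medians named here kept their sign.

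Cauda, the last part of the epididymis, was richer than the other tissues in miRNA hairpins (8 of 11 higher, median 2.68) and snRNAs (18 of 26 higher, median 1.88), and poorer in mitochondrial tRNAs (15 of 21 lower, median −1.42) and snoRNAs (41 of 105 lower). The hairpin Gm24245 was higher by 6.70 ± 0.46, the snRNA Gm22220 (chromosome 12, 54239238 to 54239386) by 5.59 ± 0.27 and Gm26461 (chromosome 9, 88553236 to 88553525) by 5.28 ± 0.34. Gm26461 alone took 108401 ± 55297 RPM in 18 cauda libraries, against 5772 ± 9194 in the 93 others. The lowest features were tRNA-Arg-TCT-5 (−2.92 ± 0.45), mt-tRNA-Val-TAC-1 (−2.70 ± 0.29) and the snoRNA Gm25789 (chromosome 1, 161038308 to 161038383; −2.41 ± 0.35). By edgeR 136 of 294 features were called (72 higher, 64 lower), the named ones at adjusted p of 1.16e-08 or less. With total counts (shift 0.46) 99 of 131 were higher, and the medians of these 4 classes kept their sign under each scaling.

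Cauda sperm was set apart by hairpins annotated as miRNA genes, 9 of 11 of which were higher than in the other tissues (median 4.92), and by 21 of 26 snRNAs (median 2.40) and 22 of 40 piRNA precursors. The hairpins Gm24187 (chromosome 13, 9834469 to 9834525; 5.81 ± 0.28), Gm23935 (chromosome 16, 11144125 to 11144181; 5.74 ± 0.28) and Gm24270 (chromosome 9, 56223715 to 56223771; 5.70 ± 0.29) led. Gm23935 had 67155 ± 31581 RPM in 19 sperm libraries against 3089 ± 6701 in the other 92. Summed over libraries, the counts of Gm24187 and Gm24270 differed by 6.37% and those of Gm24270 and Gm23935 by 10.997%, so these entries can list the same reads. Without Gm24187 and Gm24270 the hairpins made up 19.5% ± 7.13 of sperm reads, and without Gm47295 and Gm47301 as well 9.98% ± 4.38. The lowest were Gm24148, with 2 reads in sperm (ratio 26.03, interval 7.19 to 215; 862 of the 1287 other reads were from testis), tRNA-Glu-CTC-1 (−4.38 ± 0.37; 2862 ± 1994 RPM against 42741 ± 30532) and tRNA-Arg-TCT-5 (−4.01 ± 0.53), and 14 of 21 mitochondrial tRNAs were lower. The edgeR fit called 191 of 294 (102 higher, 89 lower), with adjusted p of 1.85e-06 or less for the named features. Total counts (shift 0.40) gave 128 of 195 higher and RLE (shift 1.03) 152 of 196. The snoRNAs, 50 of 105 of which were lower, had a median of −0.97 that turned to 0.24 with RLE.

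Sperm differed from testis, the organ in which they form, by far fewer piRNA precursor reads, with 35 of 40 lower and a median of −4.96. The 3 lowest stood at −6.58 ± 0.54, −6.30 ± 0.59 and, for 9-qC-31469.1, −6.19 ± 0.50. The precursor 9-qC-31469.1 had 15.0 ± 53.7 RPM in sperm and 1175 ± 1005 in testis (n = 19 each). Higher in sperm were the hairpins Gm47301 (chromosome 4, 149817764 to 149817823; 6.27 ± 0.42), which lies within the 5S ribosomal RNA gene n-R5s193 on the same strand and has the same 81162 reads, so that both cannot be separated, and Gm23935 (5.86 ± 0.52) and the U3 snoRNA Rnu3b1 (5.95 ± 0.45), which acts in ribosomal RNA processing, while 68 of the 105 snoRNAs were lower. The edgeR fit called 223 of 294 (88 higher, 135 lower), and the named features had adjusted p of 4.57e-16 or less. Total counts (shift −0.65) gave 56 of 211 higher, and the medians of piRNA precursors (−5.97 and −5.15) and snoRNAs (−2.43 and −1.36) stayed below 0 with both other scalings.

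Against the cauda epididymis, in which they are stored, sperm had more of 17 of 40 piRNA precursors and of 8 of 11 miRNA hairpins, and less of 25 of 74 cytosolic tRNAs, with 11 snRNAs higher and 11 lower of 26. The tRNA that carries selenocysteine, tRNA-SeC-TCA-1, was higher by 3.30 ± 0.37 (8267 ± 3683 against 948 ± 828 RPM, n = 19 and 18). One piRNA precursor was higher by 3.43 ± 0.73, on 20 reads in sperm and 4 in cauda (45.8 ± 68.0 against 1.87 ± 6.22 RPM). Another, with 8 reads in sperm and 0 in cauda, was at least 7.05-fold higher, and had 1554 reads in testis. Both changes rest on few reads, so their sizes are uncertain. The lowest were tRNA-Glu-CTC-1 (−3.48 ± 0.38), the snRNA Gm22220 (−3.40 ± 0.42) and tRNA-Asp-GTC-2 (−2.92 ± 0.34). The edgeR fit called 131 of 294 (66 higher, 65 lower), with adjusted p of 0.000567 or less for the named features. RLE moved the median of all features by 0.94 and gave 133 of 153 higher, and the median of cytosolic tRNAs turned from −0.39 to 0.44.

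From caput to cauda epididymis, 25 of 26 snRNAs (median 2.55) and 9 of 11 miRNA hairpins (median 4.56) were higher in cauda and 62 of 105 snoRNAs (median −1.30) were lower. The hairpin Gm24245 (7.46 ± 0.83), the RNase P RNA Rpph1, which trims tRNA precursors (chromosome 14, 50807449 to 50807767; 5.84 ± 0.67), and Gm26461 (5.78 ± 0.61) were highest in cauda, with 409 ± 273 RPM of Rpph1 in cauda (n = 18) and 32.8 ± 100.3 in caput (n = 19). The snoRNAs Gm22193 (−3.61 ± 0.48) and Gm24148 (−3.31 ± 0.69) and tRNA-Glu-TTC-2 (−3.25 ± 0.42) were lowest. By edgeR 186 of 294 features were called (106 higher, 80 lower), with adjusted p of 1.23e-05 or less for the named ones. Only the call of Gm24148 was lost among them when just the control diets were used (−1.47, adjusted p 0.207), and total counts and RLE shifted the median by 0.10 and 0.21. The columns of caput carry the numbers 11 to 29 after an S, which repeat those of cauda (10 to 28), so these tissues can stem from separate runs of numbering and no value within one run can be given.

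On the low-protein diet, liver had less of most cytosolic tRNAs. Of 70 tested, 52 fell and none rose, with a median log2 fold change of −2.43, among them all 7 serine, all 5 threonine and 9 of 10 arginine tRNAs. The largest falls were those of tRNA-Cys-GCA-1 (−6.27 ± 0.74; 8.66 ± 10.6 RPM in 5 libraries against 1064 ± 276 in 4) and tRNA-Met-CAT-2 (−5.65 ± 0.86), and tRNA-Arg-ACG-1 had 1 read on the low-protein diet and 355 on the control diet, a ratio of 267 (interval 47.6 to 10569). Of 84 snoRNAs 13 rose, led by Gm22680 (chromosome 19, 8725341 to 8725409; 3.82 ± 0.66, 605 ± 422 against 41.2 ± 18.1 RPM) and Gm22193 (3.46 ± 0.66), and the Y RNA Rny1 (chromosome 6, 47788069 to 47788180), a partner of the Ro60 protein, rose by 3.13 ± 0.74. The edgeR test called 73 of 205 features (20 up, 53 down), the named ones at adjusted p of 0.00246 or less. The list of cytosolic tRNAs fell with camera (56 adjusted over the list alone; adjusted p = 1.8e-37) and with an estimated correlation (adjusted p = 0.0306 with an estimated correlation). The other 9 lists called in liver lost the call with an estimated correlation: essential amino acid tRNAs (20 of 25 down, 23 adjusted over the list alone; adjusted p = 0.374 with an estimated correlation), other amino acid tRNAs (32 of 44 down; 0.295), branched-chain tRNAs (10 of 14 down; 0.442), arginine (0.341), leucine (0.447), serine (0.505) and threonine tRNAs (0.374), snoRNAs (8 adjusted over the list alone; 0.374) and snRNAs (2 of 7 up; 0.395). The median of all features was 0.13, and total counts and RLE moved it by −0.25 and −0.17. The columns carry the numbers 1 to 4 for the control diet and 48 to 52 for the low-protein diet after an S, and whether these numbers belong to 1 run of numbering is not given in the sources used here. Against the high-fat control, numbered 44 to 47 and shallower (median 12002.5 reads), edgeR called 0 features of the low-protein liver, with 12 at unadjusted p under 0.05, and no other tool was run. The share of cytosolic tRNAs was lower than in that high-fat control (21.9% ± 7.15, n = 5, against 39.9% ± 3.36, n = 4; exact permutation p 0.0159, unadjusted).

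Heart, the tissue with the deepest libraries, had the most calls on the low-protein diet. Of 93 cytosolic tRNAs 77 fell and 4 rose (median −3.14), all 22 tRNAs for branched-chain amino acids fell, and 15 of 21 mitochondrial tRNAs fell (median −2.10) with 1 rising. The share of reads from cytosolic tRNAs was not lower, at 28.4% ± 20.9 against 22.3% ± 0.977 (n = 5 each; exact permutation p 0.571, unadjusted). It was 5.34% and 7.30% in low-protein replicates 1 and 2 and 36.5% to 52.1% in replicates 3 to 5, with 36.3% from tRNA-Asp-GTC-1 in replicate 3. In contrast 9 of 10 miRNA hairpins, 11 of 13 snRNAs and 40 of 84 snoRNAs rose, and 2 snRNAs and 7 snoRNAs fell. The largest falls were those of tRNA-Leu-TAA-2 (−6.27 ± 0.68), tRNA-Asn-GTT-3 (−6.15 ± 0.63; 8.72 ± 16.7 against 989 ± 85.2 RPM, n = 5 each) and tRNA-Arg-CCG-3 (−5.87 ± 0.64). Gm26461 rose by 6.76 ± 0.60 (702 ± 688 against 4.72 ± 2.38 RPM), Rn7s1, the RNA of the signal recognition particle (chromosome 12, 69159295 to 69159594), by 5.12 ± 0.60 and the hairpin Gm47295 (chromosome 12, 69159518 to 69159596) by 5.09 ± 0.60. Gm47295 lies on the same strand as Rn7s1 and overlaps it, so their reads cannot be separated. The edgeR test called 182 of 242 features (81 up, 101 down), the named ones at adjusted p of 5.1e-16 or less. Camera called 14 of 21 lists, all lost with an estimated correlation. Among them were cytosolic tRNAs (82 adjusted over the list alone; adjusted p = 0.292 with an estimated correlation), branched-chain (22 adjusted over the list alone; 0.374), essential (34 of 35 down; 0.341) and other amino acid tRNAs (0.395), mitochondrial tRNAs (16 adjusted over the list alone; 0.505), miRNA hairpins (9 adjusted over the list alone; 0.374), snoRNAs (0.447) and snRNAs (0.447). The queuosine tRNAs (3 of 5 down; adjusted p 0.174), DNMT2 substrates (5 of 10 down; 0.1003), mitochondrial tRNAs transcribed from the other strand (6 of 8 down; 0.0539), glutamate (3 of 5 up; 0.371), glycine (4 of 7 down; 0.293) and threonine tRNAs (0.0643) and tRNA loci (2 of 5 up; 0.0603) were not called by camera. With fry 19 of the 21 lists of heart were called. Median depth was 176730 reads on the low-protein diet and 1101120 on the control diet, and the median of all features (−0.29) moved by 0.16 and 0.22 with total counts and RLE. The columns carry 35 to 39 for the low-protein diet and 5 to 9 for the control diet, numbers that do not adjoin and whose run or runs are likewise not given, so a difference of run cannot be separated from diet. Against the high-fat control, whose columns carry no number, 101 features were called, 90 of them also called against the control diet.

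In testis no single feature passed on the low-protein diet. The edgeR and DESeq2 tests each called 0 of 447, with 40 at unadjusted p under 0.05 by edgeR. The smallest p-values belonged to tRNA-Ala-TGC-7 (−1.68 ± 0.52; 214 ± 89.0 against 353 ± 113 RPM, n = 5 each) and tRNA-Asp-GTC-2 (−1.61 ± 0.57), both at adjusted p 0.519. Camera called 20 of 22 lists, with cytosolic tRNAs lower relative to other features (106 members, median −1.23; adjusted p = 1.95e-52, and adjusted p = 0.295 with an estimated correlation), queuosine tRNAs (median −1.33; adjusted p = 0.442 with an estimated correlation) and DNMT2 substrates (−1.61; 0.447) likewise, and 141 piRNA precursors higher (median 0.35; 0.374). None of the 20 held with an estimated correlation or with fry, and adjusted over the list alone 4 glutamine tRNAs and 1 alanine tRNA passed. Total counts moved the median of all features by 0.59 and turned the median of mitochondrial tRNAs from −0.67 to 0.26, and that of cytosolic tRNAs went to −0.30.

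In caput the low-protein diet went with fewer snoRNA and mitochondrial tRNA reads, since 23 of 65 snoRNAs and 10 of 17 mitochondrial tRNAs fell (medians −0.77 and −1.31), while 3 snoRNAs rose. Of 8 miRNA hairpins 6 rose and 1 fell. The snoRNA Gm26109 had 3 reads on the low-protein diet and 616 on the control diet, a ratio of 28.1 (interval 9.57 to 137), Gm22193 fell by 3.95 ± 0.64 (131 ± 161 against 2406 ± 879 RPM, n = 5 each) and mt-tRNA-Asp-GTC-1 fell by 3.38 ± 0.61. Mir6236 rose by 3.05 ± 0.71 (599 ± 447 against 64.2 ± 56.8 RPM), on only 20 reads in all low-protein libraries together and 15 in all controls. The proline tRNAs tRNA-Pro-AGG-1 (3.03 ± 0.73; 15 reads against 11) and tRNA-Pro-CGG-1 (2.88 ± 0.66; 20 against 16) rose as well, also on few reads. In 3 of 5 low-protein libraries they lay above and in 2 below every control. Without low-protein replicate 5 both lost their calls (1.99 and 1.68; adjusted p 0.0970 and 0.117). Of 42 cytosolic tRNAs 6 rose and 4 fell. By edgeR 60 of 145 features were called (21 up, 39 down), the named ones at adjusted p of 0.000671 or less, and in a fit of these 2 groups alone 32 were. Camera called 6 of 12 lists, none with an estimated correlation: mitochondrial tRNAs (11 adjusted over the list alone; adjusted p = 0.447 with an estimated correlation) and their heavy-strand part (0.447), miRNA hairpins (7 adjusted over the list alone; 0.374), snoRNAs (26 adjusted over the list alone; 0.447), cytosolic tRNAs (0.618) and other amino acid tRNAs (0.588). For the last 2 the test pointed up although the medians were −0.22 and −0.10, and these medians turned to 0.14 and 0.25 with total counts and to 0.07 and 0.15 with RLE. Depth was low, at a median of 5438 reads on the low-protein diet and 65559 on the control diet, and without the libraries under 5000 reads 54 features were called. Total counts and RLE moved the median of all features (−0.44) by 0.27 and 0.15. The columns carry 11 to 15 for the control diet and 21 to 25 for the low-protein diet, which do not adjoin. Those of the high-fat control, 16 to 20, lie between them.

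In cauda no feature passed with edgeR on the low-protein diet (0 of 218, with 45 at unadjusted p under 0.05), while DESeq2 called 17 and a fit of the 2 groups alone 36. The nearest were the snoRNA Snord66 (chromosome 16, 20684239 to 20684313; −2.76 ± 0.67) and mt-tRNA-Arg-TCG-1 (chromosome M, 9808 to 9875; 1.97 ± 0.50), both at adjusted p 0.0504, the latter at 8542 ± 1692 RPM in 4 low-protein and 2059 ± 1488 in 5 control libraries. Over all libraries mt-tRNA-Arg-TCG-1 had 468611 reads and its second name, mt-Tr, 25789, so its level is uncertain. Without control replicate 3 both passed (adjusted p 0.0499) with 3 calls in all, without control replicate 1 Snord66 alone did, and total counts and RLE gave 3 calls each, 2 of them up. Camera called 12 of 18 lists, among them mitochondrial tRNAs as higher (median 0.79, 8 of 20 adjusted over the list alone; adjusted p = 0.384 with an estimated correlation) and cytosolic tRNAs as lower (median −0.91; adjusted p = 0.374 with an estimated correlation), and none of the 12 held with an estimated correlation. With fry 1 held, the heavy-strand mitochondrial tRNAs (adjusted p 0.0421). The median of all features was −0.23 and moved by 0.12 with either other scaling.

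In cauda sperm no feature passed on the low-protein diet. EdgeR and DESeq2 called 0 of 180, and edgeR found 0 at unadjusted p under 0.05. The snRNA Gm23472 (chromosome 1, 72236946 to 72237136) had the smallest p among the abundant features, with 9946 ± 6609 RPM against 3593 ± 1554 (log2 1.24 ± 0.63, n = 5 each), followed by Snord55 (chromosome 4, 117155770 to 117155848; −1.80 ± 1.00), both at adjusted p 0.988. Camera called 3 of 16 lists, snRNAs (31 members), miRNA hairpins (12) and leucine tRNAs (10), none of which held with an estimated correlation (adjusted p = 0.494, 0.596 and 0.494 with an estimated correlation). For snRNAs and miRNA hairpins the test and the median differed in sign, with medians of −0.02 and 0.04 that became 0.07 and −0.03 with total counts. Median depth was 17907 and 32090 reads.

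The share of reads from mitochondrial tRNAs differed between the low-protein and the control diet in 3 tissues. In liver it was 65.5% ± 9.76 (n = 5) against 26.5% ± 3.22 (n = 4), higher in 5 of 5 libraries than in every control. In cauda it was 10.1% ± 1.90 (n = 4) against 4.95% ± 1.46 (n = 5), higher in 4 of 4, and in caput 23.5% ± 8.64 against 46.2% ± 6.96 (n = 5 each), lower in 5 of 5. All 3 differences had a 2-sided exact permutation p of 0.00794, the smallest these designs can give, and an adjusted p of 0.0159 over 6 tissues. Without any 1 of the low-protein libraries of liver or the control libraries of cauda the adjusted p was 0.0571, as 4 against 4 libraries allow no exact permutation p under 0.0286. In heart the share was 62.6% ± 22.01 against 76.6% ± 1.21 (adjusted p 0.257), with 2 low-protein libraries above every control (82.4% and 87.3%) and 3 below (36.7% to 60.2%), in testis 18.8% ± 4.53 against 15.1% ± 3.24 (0.250) and in sperm 14.3% ± 6.37 against 16.9% ± 11.6 (0.635), by the same exact test. In sperm the difference of −2.60 percentage points became 1.18 without control replicate 2. In liver the share of cytosolic tRNAs was 21.9% ± 7.15 against 63.01% ± 9.09. Per feature, 2 of 21 mitochondrial tRNAs rose in liver and 1 fell (median 0.82; camera adjusted p 0.116, and adjusted p = 0.807 with an estimated correlation). Against the high-fat control, the low-protein share of mitochondrial tRNAs was 65.5% against 45.4% in liver, 23.5% against 26.1% in caput and 10.1% against 9.48% in cauda (exact permutation p 0.0159, 0.548 and 0.738). The high-fat control itself differed from the control diet in these tissues (exact permutation p 0.0286, 0.00794 and 0.0317, all 6 unadjusted). On the high-fat diet no tissue passed. The share in heart was 64.4% ± 6.98 (n = 4) against 79.2% ± 5.48 (n = 5; exact permutation p 0.0238, adjusted 0.143), and passed (adjusted p 0.0476) when mt-tRNA-Val-TAC-1 was left out. In sperm it was 4.67% ± 0.797 against 9.94% ± 4.96 (adjusted p 0.262), in testis 10.6% ± 3.04 against 12.7% ± 1.74, in caput 20.1% ± 6.76 against 26.1% ± 4.08 and in cauda 14.6% ± 7.85 against 9.48% ± 3.02 (adjusted p 0.286 each, exact permutation). In liver it was 41.03% ± 31.7 against 45.4% ± 3.26 (adjusted p 0.686), with 2 libraries above and 2 below every control. The liver difference of −4.37 points became 4.07 without high-fat replicate 3 and 5.43 without replicate 4.

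**Figure D2:**
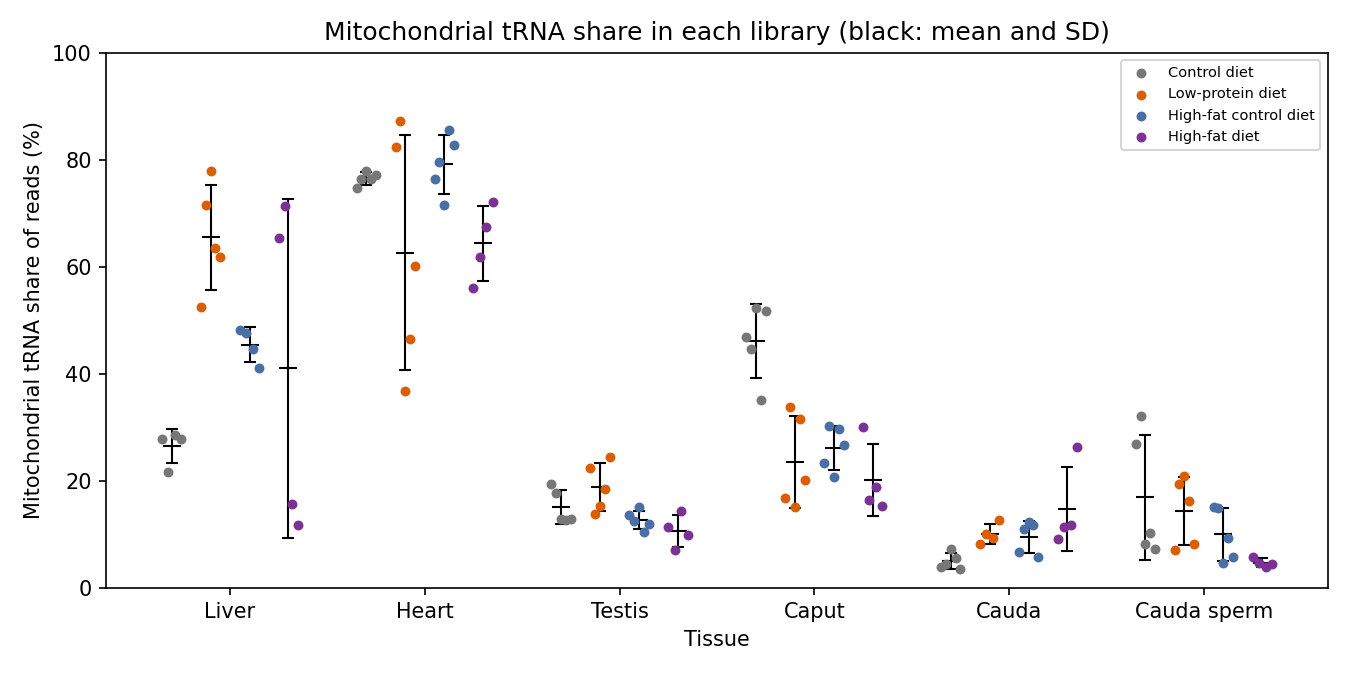
Percent of reads from mitochondrial tRNAs in each library (points), with mean and SD, by tissue and diet. Low-protein liver (65.5%) and cauda (10.1%) lie above their controls (26.5% and 4.95%) and low-protein caput (23.5%) below (46.2%).

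On the high-fat diet few features passed in any tissue. In liver Rn7s1 (4.04 ± 1.11; 123859 ± 143476 against 17928 ± 2225 RPM, n = 4 each), the overlapping hairpin Gm47295 (4.10 ± 1.08) and CT010467.1, annotated as ribosomal RNA (chromosome 17, 39846353 to 39848827), rose, and CT010467.1 had 174 reads on the high-fat diet and 2 on the high-fat control (ratio 7.60, interval 2.07 to 63.3). The fit called 6 of 205 features (5 up, 1 down; adjusted p 0.0462 for each named one), the others being Snord66 (3.98 ± 1.007), the mitochondrial ribosomal RNA mt-Rnr1 (3.37 ± 0.89) and the snoRNA Gm22571 (−3.39 ± 0.94), which were singled out after their values were seen. Rn7s1 and Gm47295 lay above every control in 2 libraries and below every control in 2. DESeq2 called 12, with 53 at unadjusted p under 0.05 in edgeR. Total counts, which moved the median of all features from 1.06 by −1.41, called 2 with 0 up, and RLE (shift −0.23) called 0. Leaving out high-fat control replicate 1 gave 1 call and replicates 2, 3 or 4 gave 0, and leaving out high-fat replicates 1, 2, 3 (827 reads) or 4 gave 14, 24, 22 and 0. Without high-fat replicate 4 Rn7s1 stood at 1.16, Gm47295 at 1.25 and CT010467.1 at 2.63. Camera called 3 lists, DNMT2 substrates lower, with median −0.55 (adjusted p = 0.927 with an estimated correlation), and miRNA hairpins and leucine tRNAs higher, with medians of 2.43 and 1.95 (0.927 each); 8 of the 9 hairpins passed adjusted over the list alone.

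In heart tRNA-Gly-CCC-2 (2.44 ± 0.58; 51.3 ± 22.2 against 6.50 ± 7.63 RPM) and tRNA-Gly-CCC-3 (2.004 ± 0.52) were higher on the high-fat diet and the snoRNA Gm24148 was lower (−2.39 ± 0.61), with adjusted p 0.00667, 0.0102 and 0.0102. All 3 fall outside the naming rule and were singled out after their values were seen. EdgeR called these 3 of 242 features, with 31 at unadjusted p under 0.05, and DESeq2, total counts and RLE called 2 each, both up with the scalings. The count was 6, 0 and 1 without high-fat control replicates 2, 3 and 5, and 17 and 14 without high-fat replicates 1 and 4. It was 0 with counts summed per anticodon and 0 with all entries as deposited. All 5 glutamate tRNAs passed adjusted over the list alone (median 1.38; camera adjusted p 4.2e-06, adjusted p = 0.709 with an estimated correlation), and camera called 7 of 21 lists in all, none with an estimated correlation, with snoRNAs tested as lower (adjusted p = 0.927 with an estimated correlation) although their median was 0.21.

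In the reproductive tract 1 feature passed on the high-fat diet, tRNA-Glu-TTC-2 in caput (1.79 ± 0.47; 115744 ± 61240 RPM in 4 libraries against 29691 ± 2706 in 5, above every control in 3 of 4; adjusted p 0.0414). It was the single call of edgeR among 145 features, with 25 at unadjusted p under 0.05 and 6 calls by DESeq2, total counts or RLE. It lost the call without high-fat control replicate 2 (1.68, adjusted p 0.139) and without high-fat replicates 2 (adjusted p 0.210) or 4 (1.57, 0.153), and also with no filter (0.226) or without the libraries under 5000 reads (0.0501). The count was 7, 0, 9, 14 and 11 without high-fat control replicates 1 to 5 and 24, 0, 2 and 0 without high-fat replicates 1 to 4. In testis edgeR called 0 of 447 (19 at unadjusted p under 0.05; DESeq2 called 2), with the mitochondrial mt-tRNA-Ser-TGA-1 (chromosome M, 6870 to 6938; −2.27 ± 0.53, adjusted p 0.113) and mt-tRNA-Glu-TTC-1 (14071 to 14139; −1.33 ± 0.41, 0.535) nearest. Both lay below every control in 4 of 4 libraries. In cauda edgeR and DESeq2 called 0 of 218 (18 at unadjusted p under 0.05), with mt-tRNA-Leu-TAG-1 (11671 to 11741; 1.89 ± 0.53) and Snord65 (chromosome 11, 62604515 to 62604586; 2.07 ± 0.60) nearest at adjusted p 0.147. Without high-fat control replicate 2, high-fat replicate 1 or high-fat replicate 4 there were 2, 7 and 1 calls in cauda. In sperm edgeR and DESeq2 called 0 of 180 (6 at unadjusted p under 0.05), with tRNA-Glu-CTC-1 (1.87 ± 0.67; 4894 ± 3213 against 1447 ± 821 RPM) and mt-tRNA-Leu-TAG-1 (2 reads against 35; ratio 13.2, interval 3.39 to 113) at adjusted p 0.901. Camera called lists with piRNA precursors of testis lower (141 members, median −0.63; adjusted p = 0.709 with an estimated correlation), mitochondrial tRNAs of cauda higher (20 members, 0.59; 0.927) and mitochondrial tRNAs of sperm lower (18 members, −0.89; 0.709). None of the 31 list and tissue pairs called on the high-fat diet held with an estimated correlation or with fry, whose smallest adjusted p was 0.612. Total counts moved the median of all features by 0.14 in cauda and −0.26 in sperm, and RLE by 0.20 in caput.

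**Figure D3:**
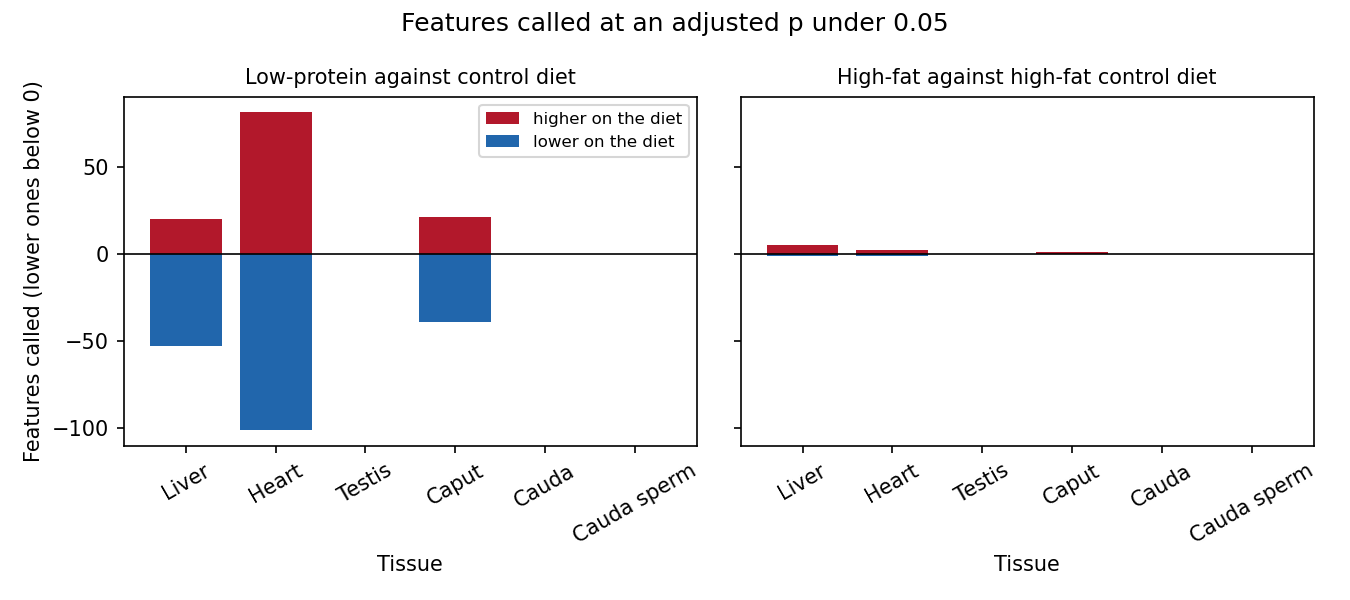
Number of features called higher or lower (edgeR, adjusted p under 0.05) per tissue for both diet effects. The low-protein diet gave 182 calls in heart, 73 in liver and 60 in caput and 0 in testis, cauda and sperm, and the high-fat diet at most 6.

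The difference between low-protein and control libraries varied among the tissues. By a test of the tissue by diet terms, 154 of 460 features differed (190 at unadjusted p under 0.05), among them 60 of 98 cytosolic tRNAs, 15 of 21 mitochondrial tRNAs, 27 of 51 snRNAs and 33 of 141 snoRNAs, and 0 of 111 piRNA precursors. Gm22193, which rose in liver and fell in caput, differed at adjusted p 9.7e-07, and tRNA-Arg-CCG-3 at 1.0e-09. Without liver and heart, where the column numbers of both diets do not adjoin, 16 features differed, and differences that involve these 2 tissues cannot be put down to diet alone. In caput the numbers do not adjoin either, at 11 to 15 for the control and 21 to 25 for the low-protein diet. The high-fat control lies between them at 16 to 20. The mitochondrial tRNA share moved in opposite directions in liver and caput, by 39.02 and −22.7 percentage points, and its effects differed by 61.7 points (permutation of diet labels within tissue, adjusted p 0.000236 over 15 tissue pairs). For the high-fat diet 17 of 460 features differed, with 94 at unadjusted p under 0.05, among them 5 of 21 mitochondrial tRNAs. RLE factors gave 3, total counts 9 and the libraries over 5000 reads 56.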

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

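The tests of column numbering, including that of the cytosolic tRNA share, of the diet as the whole cause in liver and heart and of control libraries standing apart in cauda were chosen only after the result was seen, as was the restriction of the caput axis test to called features.

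In liver and heart the low-protein diet gave 73 and 182 calls, and chance can be excluded in both, as 100 splits of the same libraries gave at most 70 and 71 otherwise. Most of these calls did not rest on the number of control reads. With the control libraries thinned to the low-protein depth, 71 of 204 and 140 of 176 features were called, 61 of the 73 and 115 of the 182 among them. The median absolute log2 change of the called features then stood at 1.006 and 0.9501 of its value. Thinning keeps the expected proportions of features, so that ratio cannot decide whether other traits of shallow libraries played a part. A cause found only in the low-protein diet is argued against for the whole set of calls. The high-fat control, itself another diet, was set against the control diet. There 47 of the 73 liver and 126 of the 182 heart calls were called the same way. Independent lists, which have no controls in common, would share 11.8 and 51.7. Simulated unchanged groups shared 0, but they hold no change to call, so this 0 cannot decide the question. Split controls gave 22 to 38 and 116 to 126 (6 and 10 splits), and the covariance was 4.84 and 5.39 against 0.280 and 0.0945 simulated. The control libraries thus differ from both groups, which does not show whether diet or the libraries are the cause. Control libraries from another run of numbering cannot be excluded for the falls of cytosolic tRNAs in liver. The share of these tRNAs was 21.9% ± 7.15 (n = 5) against 39.9% ± 3.36 (n = 4) in the high-fat control (exact permutation p 0.0159, unadjusted). The numbers of that control, 44 to 47, adjoin those of the low-protein libraries, 48 to 52, but this does not show a shared run. The same numbers recur in high-fat sperm and control testis. Diet and numbering cannot be told apart in either tissue, because the runs are not given. Low-protein against high-fat control gave 0 calls in liver (edgeR, 12 at unadjusted p under 0.05, no other tool run, median depth of that control 12002.5 reads). It gave 101 in heart, where that control carries no number. An effect of diet stays open in both tissues.

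In caput the low-protein diet gave 60 calls against at most 18 in the other splits, so chance can be excluded. Thinned controls left the median change of the called features at 0.964 of its value (absolute log2 of 2.15 ± 0.757, SD over features, before and 2.07 ± 1.13 after). Thinning keeps the expected proportions of features, so this ratio cannot decide whether lower depth or another trait of shallow libraries played a part. Only 34 of 98 features were then called and 27 of the 60 kept their call, since 42 of them passed the filter and the median standard error rose from 0.511 to 0.624. An axis along which libraries of a group differ in liver and heart (41.1% of the variance within groups over 35 libraries) cannot be told apart from diet: across 142 features, which are not independent replicates, the absolute Pearson r was 0.143 (rho 0.136), a value that met the bound set beforehand for excluding it but dilutes the called features, and over the 57 called ones it was 0.231, which met no bound. The high-fat control against the control diet shared 12 of the 60 calls (independent lists 5.92, split controls 13 to 25). Simulated unchanged groups, which hold no change to call, shared 0. Low-protein against high-fat control gave 62 calls, 35 of them among the 60. The diet itself stays among the open explanations.

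The mitochondrial tRNA share of cauda was higher on the low-protein diet. Other RNA classes taking more of the control reads are argued against, since within tRNA reads alone the mitochondrial share was 25.6% ± 0.926 (n = 4) against 13.6% ± 4.42 (n = 5; exact permutation p 0.00794). Control libraries that stand apart from the other diets are a candidate explanation, as the share of all reads was also higher in the high-fat control (9.48% against 4.95%; exact permutation p 0.0317) and did not pass between low-protein and high-fat control (exact permutation p 0.738). Within tRNA reads the high-fat control was at 18.2% ± 6.73 and did not pass against the control diet (exact permutation p 0.246). An effect of diet stays open.

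Chance can be excluded for each tissue contrast, with the real count and the highest of the other splits at 108 and 54 for liver, 115 and 74 for heart, 173 and 59 for testis, 139 and 80 for caput, 136 and 40 for cauda, 191 and 65 for sperm, 223 and 51 for sperm against testis, 131 and 48 for sperm against cauda, and 186 and 81 for cauda against caput. For the 3 high-fat calls of heart chance cannot be excluded firmly. As many calls came from 3 of 100 splits, the real one included (highest other 8). This met the bound set beforehand but was not adjusted over the comparisons tested. The count was 0 without high-fat control replicate 3 and 17 without high-fat replicate 1. For the 154 features whose low-protein effect differed between tissues, only the real one of 40 splits gave as many (highest other 119). With so few splits and no adjustment over the comparisons tested, chance cannot be excluded firmly there either. Chance cannot be excluded for the 6 high-fat calls of liver (39 in 35 splits, of which 6 gave as many), the 1 call of caput (30, with 6 of 100 splits giving as many) or the 17 features whose high-fat effect differed between tissues (35 in 40 splits, of which 4 gave as many). A count of 0 cannot be set apart from chance, and the highest other count was 148 for low-protein testis, 5 for cauda and 77 for sperm, and 0, 43 and 0 for the high-fat diet in these tissues. In edgeR these 6 comparisons had 40, 45, 0, 19, 18 and 6 features at unadjusted p under 0.05, and DESeq2 called 0, 17, 0, 2, 0 and 0. Some splits called several times the real count, as in high-fat liver (39 against 6) and caput (30 against 1), while the median of the other splits was 0 in both. Such maxima cannot decide whether the samples hold a structure that diet does not describe, which was not tested. Where the real count is 0 any call exceeds it, so the 148, 77 and 43 calls of low-protein testis and sperm and high-fat cauda show only that some splits call many features. In the high-fat comparisons taken as paired, 2 of 12 splits of caput and 12 of 12 of cauda that part as many pairs gave as many calls.

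Single libraries stood far from their group in 10 of 116 tests, each of 1 share or named feature in 1 group of tissue and diet. Chance gives about 1 in 20 for independent values with a normal spread. The same libraries were tested many times, so that rate is only a rough guide. Also, 2 of the 10 rest on 1 and 2 reads, which counting noise alone can give. The mitochondrial tRNA share was 21.7% in control liver replicate 2 against 27.8% to 28.6% in the others, and 26.3% in high-fat cauda replicate 4 against 9.15% to 11.8%. In control liver replicate 1 had 143 RPM of Rny1 (others 8.65 to 26.7) and replicate 4 had 1476 RPM of tRNA-Cys-GCA-1 (903 to 970). Those on 1 and 2 reads are in low-protein liver, where replicate 2 had 10.2 RPM (1 read) of tRNA-Arg-ACG-1 (others 0) and replicate 1 had 79.9 (2 reads) of tRNA-Met-CAT-2 (0 to 8.20). Low-protein heart replicate 5 had 38.3 RPM of tRNA-Asn-GTT-3 (0 to 5.33), control cauda replicate 3 had 4631 of mt-tRNA-Arg-TCG-1 (845 to 1901), high-fat liver replicate 4 had 2430 of CT010467.1 (0 to 91.4) and high-fat control cauda replicate 2 had 449.9 of Snord65 (0 to 116).

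The diet effect differed between tissues for 27 of the 32 named features, by adjusted p of the tissue by diet terms in edgeR. These features had been named for their change in 1 tissue, which favours a difference. Over all features 154 of 460 differed on the low-protein diet, and 16 without liver and heart. The tRNAs among the named ones were tRNA-Pro-AGG-1 (2.33e-10), tRNA-Pro-CGG-1 (6.81e-10), tRNA-Arg-CCG-3 (1.004e-09), tRNA-Asn-GTT-3 (6.30e-08), tRNA-Cys-GCA-1 (2.09e-07), tRNA-Leu-TAA-2 (6.01e-07), tRNA-Arg-ACG-1 (3.51e-06), tRNA-Met-CAT-2 (1.49e-05), mt-tRNA-Asp-GTC-1 (3.54e-05) and mt-tRNA-Arg-TCG-1 (8.31e-05). The other RNAs were Gm26461 (9.17e-08), Gm22193 (9.67e-07), Gm22680 (7.84e-06), Rn7s1 (9.33e-06), Gm26109 (2.47e-05), Gm47295 (2.91e-05), Gm23472 (0.00108), Mir6236 (0.001095), Snord66 (0.00530), Rny1 (0.00812) and Snord55 (0.0115). On the high-fat diet 17 of 460 features differed, among them mt-tRNA-Leu-TAG-1 (0.000982), CT010467.1 (0.00279), Gm47295 and Rn7s1 (0.00649 each), mt-tRNA-Glu-TTC-1 (0.0320) and mt-tRNA-Ser-TGA-1 (0.04997). The differences of tRNA-Ala-TGC-7 (0.845) and tRNA-Asp-GTC-2 (0.118) on the low-protein diet and of Snord65 (0.190), tRNA-Glu-TTC-2 (0.0817) and tRNA-Glu-CTC-1 (0.0705) on the high-fat diet did not pass.

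The difference of the mitochondrial tRNA share between low-protein and control libraries was higher in liver than in heart by 52.96 percentage points (adjusted p 0.00661), testis by 35.3 (0.0396), caput by 61.7 (0.000236), cauda by 33.9 (0.0417) and sperm by 41.6 (0.0163), by permutation of diet labels within each tissue. It was higher in testis than in caput by 26.5 points (0.00646), and the effect in caput minus that in cauda was −27.8 (0.000236). On the high-fat diet the effect in heart minus that in cauda was −19.96 points (0.0472). Differences that involve liver, heart or caput cannot be put down to the low-protein diet alone, since the column numbers of both diets do not adjoin there. In caput the high-fat control also lay below the control diet (26.1% against 46.2%; exact permutation p 0.00794). Low-protein caput did not pass against that high-fat control (23.5% against 26.1%; exact permutation p 0.548, both unadjusted). The points also start from unlike control shares, such as 26.5% in liver and 4.95% in cauda.

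Reads on the antisense strand of tRNAs, which no comparison used, came to 68 over all libraries, in 20 of 155 such entries with at most 18 in one. There are no control samples for them, so it is not known whether they exceed a background.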

How the results depend on the processing

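The tests on all entries as deposited, those without libraries under 5000 reads, those without liver and heart and those with a block on library number were chosen only after the result was seen. No named feature that was called and no called share changed sign under any alternative run, other called features were not followed one by one, and medians of lists that camera called did, as that of mitochondrial tRNAs in low-protein testis (−0.67, and 0.26 with total counts). Of the values for 88 named features, 941 under alternatives kept their direction and side of the threshold, 45 lost significance and 25 gained it. Of the values for counts and shares 348 stayed, 99 moved, 15 lost significance and 1 gained it. In simulations at the real depths and spreads, 46.9% of 8-fold changes were recovered in the high-fat fit of liver and 85.7% or more in each of the other diet fits. Alternatives for shares of tRNA fragment classes were not run, because the entries have none. The cause was not tested for any change below except where named.

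DESeq2 called 17 features for the low-protein diet in cauda, 12 for the high-fat diet in liver, 2 in testis and 6 in caput, and 235 for heart against the other tissues. RLE factors gave 3 in low-protein cauda, 0 in high-fat liver, 6 in high-fat caput, 197 for heart and 3 high-fat differences between tissues. Total counts gave 3, 2, 6, 236 and 9 for the same results. Summing per anticodon, which tests fewer features, gave 2 in low-protein cauda and 27, 0 and 7 in high-fat liver, heart and caput. A fit of only the 2 groups gave 32 in low-protein caput and 36 in cauda, and 0, 13, 1 and 6 in high-fat liver, heart, testis and caput. Without the filter on low counts the low-protein diet gave 128 in liver, 291 in heart and 11 in cauda, the high-fat diet 38 in cauda, and 10 high-fat differences between tissues. The tissue contrasts then gave 192 for liver, 264 for heart, 479 for testis, 281 for caput, 428 for cauda, 541 for sperm, 602 for sperm against testis, 317 for sperm against cauda and 477 for cauda against caput, with more features tested. With all entries as deposited, which count the same reads under several names, the low-protein diet gave 283 in heart and 140 in caput, and the high-fat diet 0 in liver, 0 in heart, 7 in caput and 14 in cauda. The tissue contrasts gave 173 for heart, 318 for testis, 225 for caput, 320 for sperm, 361 for sperm against testis, 246 for sperm against cauda and 290 for cauda against caput. Without libraries under 5000 reads the high-fat diet gave 22 calls in liver and 0 in caput, 56 differences between tissues, and a difference of the mitochondrial tRNA share in liver of 4.07 points. Without liver and heart 16 features differed between tissues on the low-protein diet and 2 on the high-fat diet, with fewer libraries fitted. Camera called 65 low-protein and 31 high-fat list and tissue pairs, which became 1 and 0 with an estimated correlation. The fry test, which asks whether a list changed at all, called 37 and 0 pairs, with more in heart (19 against camera's 14) and liver (12 against 10). Without the most abundant feature the high-fat difference of the mitochondrial tRNA share was −13.2 points in heart, which passed (adjusted p 0.0476), and 0.393 in liver.

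Replicate numbers were taken to pair the libraries only in the high-fat comparisons of caput and cauda, where the block changed no call. No label gives such a pairing. In cauda only 1 of the 4 pairs held the best correlation of its library, and in caput 3 did. Elsewhere the libraries share only a number. The replicate block there gave 47 calls in low-protein liver, 7 in low-protein cauda, 0 in high-fat liver and 5 high-fat differences between tissues, and it changed no other count by more than 1.5 times. In high-fat liver 4 of 4 libraries correlated best with their own replicate number, but by library number 1 of 3 pairs correlated above 0.1. A block on library number, where it differs, gave 51 calls in low-protein liver, 14 in low-protein cauda and 0 in high-fat liver. Permuting the mitochondrial tRNA share within replicate numbers gave 39.9 points in liver, −22.7 in caput and 4.78 in cauda, each at adjusted p 0.250, where few pairs limit the p that can be reached. Within library numbers it gave 42.3 points in liver and 4.88 in cauda, also at adjusted p 0.250. Across tissues 101 of 270 same-numbered pairs correlated above 0.1 (mean r −0.0229).

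Leaving out each library in turn gave 0 to 3 calls in low-protein cauda, and 0 to 24, 0 to 17, 0 to 24 and 0 to 7 in high-fat liver, heart, caput and cauda. The difference of the mitochondrial tRNA share ranged from 35.9 to 42.3 points in low-protein liver, where it missed the threshold (adjusted p 0.0571) without any of the low-protein replicates, and from 4.26 to 5.75 in low-protein cauda, where it did so without any of the control replicates, because 4 against 4 libraries allow no lower p than 0.0286. It ranged from −5.03 to 1.18 in low-protein sperm and from −14.5 to 5.43 in high-fat liver.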

Other observations

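The tests of diets outside the planned effects, from fits of every pair of diets in each tissue, and those of the mitochondrial share within tRNA reads were chosen only after the result was seen. Testis had more calls between the 2 control diets than for either tested diet effect, both of which had 0 in edgeR (40 and 19 at unadjusted p under 0.05; DESeq2 called 0 and 2). In the high-fat control against the control diet, 97 of 106 cytosolic tRNAs and 17 of 21 mitochondrial tRNAs were lower and 61 of 141 piRNA precursors were higher, with median log2 fold changes of −3.32, −2.24 and 1.24. Among the smallest p-values were those of tRNA-Gly-CCC-1 (−4.33 ± 0.78; 345 ± 40.7 against 2085 ± 1312 RPM, n = 5 each), tRNA-His-GTG-2 (−3.65 ± 0.69; 3570 ± 1480 against 14488 ± 6154) and mt-tRNA-Thr-TGT-1 (−2.80 ± 0.52; 1534 ± 305 against 3647 ± 1480), each at adjusted p 0.000874. By edgeR 209 of 447 features were called (76 higher, 133 lower). With total counts, which moved the median of all features from 0.11 to 1.11, 174 were higher and 67 lower, and these 3 medians (−1.57, −0.76 and 2.26) kept their sign, but 60 cytosolic and 7 mitochondrial tRNAs were then lower and 116 piRNA precursors higher. Cytosolic tRNAs took 33.1% ± 2.78 of reads against 62.8% ± 18.1 (exact permutation p 0.0238), and mitochondrial tRNAs 12.7% ± 1.74 against 15.1% ± 3.24 (exact permutation p 0.198). Within tRNA reads the mitochondrial share was higher in the high-fat control, at 27.7% ± 2.56 against 20.1% ± 4.85 (exact permutation p 0.0317, all unadjusted). Median depth was 30415 reads on the high-fat control and 223942 on the control diet.

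Caput and sperm also differed between diets that the design does not set against each other. In caput 25 of 42 cytosolic tRNAs were higher in the high-fat control than in the control diet, among them tRNA-Cys-GCA-5 (2.02 ± 0.43; 777 ± 304 against 199 ± 168 RPM, n = 5 each), and the snoRNA Gm22680 was lower (−2.30 ± 0.40; 265 ± 117 against 1508 ± 433; adjusted p 3.8e-05). EdgeR called 34 of 145 features there (26 higher, 8 lower), while RLE, which moved the median from 0.02 to −0.57, called 15 higher and 45 lower, and the median of cytosolic tRNAs stayed above 0 (1.26, and 0.81 with RLE). The mitochondrial tRNA share was 26.1% ± 4.08 against 46.2% ± 6.96 (exact permutation p 0.00794, unadjusted). In sperm 7 of 18 mitochondrial tRNAs were lower on the high-fat than on the low-protein diet, led by mt-tRNA-Leu-TAG-1 (−4.96 ± 1.11; 19.1 ± 23.7 RPM, n = 4, against 675 ± 612, n = 5; adjusted p 0.00554), with a median of −1.75 that total counts moved to −2.22. The high-fat libraries held only 2 reads of mt-tRNA-Leu-TAG-1, so the size of its change is uncertain. Low-protein replicate 3 stood apart, with 68.3% of reads from cytosolic tRNAs and 20.8% from mitochondrial tRNAs. It had 2.76% from miRNA hairpins, against 17.3% to 39.7% in the others. The contrast was not run without it. EdgeR called 11 of 180 features in that contrast (1 higher, 10 lower). Within the tRNA reads of sperm the mitochondrial share was 30.6% ± 5.07 on the high-fat diet (n = 4) and 43.7% ± 6.10 on its own control (n = 5; exact permutation p 0.0159, unadjusted). In cauda 6 of 20 mitochondrial tRNAs were higher on the high-fat than on the control diet, with mt-tRNA-Arg-TCG-1 at 2.30 ± 0.50 and a median of 1.08, and Gm26461 was lower (−2.68 ± 0.59; adjusted p 0.00660 each), among 21 of 218 called (9 higher, 12 lower), or 36 higher and 5 lower with total counts. High-fat replicate 4 stood apart, with 26.3% of reads from mitochondrial tRNAs against 9.15% to 11.8% in the others. Its share of other small RNA, the class of Gm26461, was 0.897% against 11.5% to 26.7%. This contrast of cauda was not run without that library. Between the control diets edgeR called 0 features in cauda and in sperm, with 21 at unadjusted p under 0.05 in each, and no other tool was run on these contrasts.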
